A study of Mus musculus with 27 samples.

How the data were processed

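The deposited values are log2 RMA values made by the authors. Per the series text they background-corrected, quantile normalized and summarised the arrays with RMA in Arraystar, and the processing notes of the authors also name Affymetrix Expression Console and the mm9 assembly without a role. Versions are not given in the sources used here. Per the labels, total RNA was isolated with a column kit, labelled with biotin by the Affymetrix whole-transcript sense protocol and hybridised to Mouse Gene 1.0 ST arrays. Per the series text the mice are biological replicates, and per the labels they were untreated females. No date, scan day or batch is given in the sources used here.

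The deposited table holds 30177 probe sets and 27 arrays, with values from 0.70 to 13.85, and 0 of its columns were left without a sample. No further normalization was applied. The 6-week and 8-week arrays follow 2 distributions, which separate runs of RMA for each age would give, so that age and normalization are confounded. Between arrays the highest correlation was 0.9958, and no array was a copy of another.

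Probe sets were assigned to genes by the gene symbols of the deposited probe table. Of the probe sets 21789 name 1 symbol, 1621 several and 6767 none, and only the first kind was used, so transcripts read by shared probe sets were not analysed here. Symbols were compared with the RefSeq annotation of the GRCm38.p6 assembly, which updated 0 of them; 21698 of these probe sets had an Entrez identifier in it. The assembly served for names, chromosomes and the order of genes. Where a gene had several probe sets (999 genes) the one with the highest mean over all arrays was kept, which left 19938 genes, all of them tested.

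Genes were tested with limma: 1 mean per genotype and age (6 groups), 12 contrasts, moderated variances (21 residual and 5.524 prior degrees of freedom) and Benjamini-Hochberg adjustment over all genes of a contrast at 0.05. The contrasts are the 3 pairs of genotypes at each age, the 2 ages in each of the 3 genotypes and the 3 interactions. Beside each count of a contrast of 2 groups stands the number of genes whose arrays do not overlap between the groups, and the share of all genes tested.

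The contrasts, the 31 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined. Lists were tested with camera in limma (preset correlation 0.01, and with a correlation estimated for each list), which compares a list with all other genes, and with fry, which asks whether the genes of a list move on balance in 1 direction. Lists with fewer than 3 measured genes would have been left out. A list score is the mean log2 value of its genes in an array, and scores of the 8-week groups were compared by a two-sided exact permutation test over all 924 splits of the 6 and 6 mice (smallest p 0.0022), adjusted over the 31 lists. Groups of 3 against 3 cannot give a p below 0.10. Intervals of score differences hold the shifts that this test does not reject at 95%, in steps of 0.01.

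Genes named in the text follow a rule. Batf3 and Rag1 are always named. For each 8-week contrast the 10 highest and 10 lowest log2 differences are taken among genes with an adjusted p under 0.05 whose arrays do not overlap between the groups, leaving out predicted genes, RIKEN clones, microRNAs, small nucleolar RNAs and segments of immunoglobulin and T cell receptor genes. For the other contrasts 5 and 5 are taken, for interactions without the condition on overlap. Up to 4 members of each list with the greatest absolute change may be named. Other genes are said to have been chosen after their values were seen.

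The lists are given with the genes used and the genes listed. For lymphocytes they are T cell (21 of 23), cytotoxic effector (15 of 15), regulatory and checkpoint (12 of 12), NK cell (9 of 10), B cell (19 of 21) and plasma cell and immunoglobulin (9 of 18). For myeloid cells they are macrophage (20 of 22), Batf3-dependent dendritic cell (12 of 14), other dendritic cell (16 of 16) and neutrophil (12 of 12). For inflammation they are MHC class II (10 of 12) and class I presentation (11 of 15), interferon-gamma response (13 of 21), type I interferon response (21 of 23), chemokines (21 of 22), cytokines (19 of 19), leukocyte adhesion and homing (12 of 14), lymphoid tissue organization (13 of 14) and complement (11 of 13). For the tissue they are beta cell (21 of 24), other endocrine cells (11 of 13), ER stress and unfolded protein response (19 of 19), acinar (25 of 30), duct (8 of 10), Reg family (7 of 7), endothelial (12 of 12), fibroblast and stellate cell (14 of 14), adipocyte (8 of 9), Schwann cell (5 of 7), cell cycle (17 of 18) and immediate early and isolation stress (13 of 14).

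The other listed members are not reported here. Synonyms were matched for C1s, Ero1lb and Spink3.

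Alternatives fixed in advance were a filter that keeps the 11809 genes above the median probe set (5.1) in at least 3 arrays, every probe set on its own, trend and robust variances, array weights, quantile normalization across all arrays, a 2-fold threshold, the replicate number as a block, 8-week groups limited to mice 1 to 3, the acinar score as a covariate, only the groups compared in the fit, an estimated correlation and fry for lists, each array left out in turn, and the NOD arrays split between the comparisons that share them. A fit of only the arrays of the same age was added after seeing the data.

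The calls were tested on simulated data with the same 19938 genes and group sizes. At 8 weeks (6 against 6) planted log2 differences of 0.5, 1 and 2 were found in 58.2%, 98.5% and 98.5% of genes, with 8 false calls among 19738 unchanged genes. At 6 weeks (3 against 3) they were found in 35.8%, 89.6% and 100%, with 3 false calls. A planted list was called, with 0 calls among 30 other lists. No rate is given for unequal spread of groups or for correlated list genes. Calculations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.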

Results

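Islets of Langerhans, the endocrine cell clusters of the pancreas, were taken from 27 female mice on the NOD/ShiLt background, a strain that develops autoimmune diabetes. Mice of 3 genotypes were used at each of 2 ages. NOD mice carry the intact genes. Mice labelled NOD.Batf3-/- (Batf3ko here) lack the transcription factor needed by the cross-presenting dendritic cells that present antigen to CD8 T cells. Mice labelled NOD.Rag1-/- (Rag1ko here) lack the recombinase without which no mature T or B lymphocytes form. Each genotype had 3 mice at 6 weeks and 6 at 8 weeks. Total RNA of each mouse was hybridised to a whole-transcript array, giving log2 values for 30177 probe sets, reduced to 1 each for 19938 genes. The number of arrays limits the precision of every comparison, most of all at 6 weeks. Changes are given as log2 differences ± SE from a limma fit of all 27 arrays, with p-values adjusted over all genes. Scores of gene groups are mean log2 values per mouse and are given as mean ± SD.

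The arrays of the 2 ages followed 2 different distributions. The median of an array lay between 5.29 and 5.34 at 6 weeks and between 4.92 and 5.05 at 8 weeks, and the 99th percentile between 11.58 and 11.83 and between 11.17 and 11.32. Genotypes were therefore compared within an age, and every difference between ages is given with this limit.

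The engineered genes were read first. The Batf3 probe set gave 4.33 ± 0.12 (SD, n = 6) in Batf3ko islets at 8 weeks, 4.55 ± 0.31 in NOD and 4.37 ± 0.23 in Rag1ko. The difference between Batf3ko and NOD did not pass the test (log2 -0.22 ± 0.12, adjusted p = 0.28), and at 6 weeks it was 0.08 (adjusted p = 0.93). Batf3 values of single NOD mice at 8 weeks ran from 4.22 to 5.11 and those of Batf3ko mice from 4.19 to 4.54. The Rag1 probe set was higher in the arrays labelled Rag1ko at 8 weeks (3.60 ± 0.12, n = 6) than in NOD (2.79 ± 0.17; log2 for NOD minus Rag1ko -0.81 ± 0.12, adjusted p = 8.9e-05) or Batf3ko (2.95 ± 0.21; -0.66, adjusted p = 0.0063). At 6 weeks the same difference from NOD was -0.51 ± 0.17 (adjusted p = 0.095, 3 mice per group). Where these probe sets lie relative to the altered part of either gene is not given in the sources used here, so neither value checks a genotype, and every direction below rests on the genotypes as labelled.

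The comparison of islets labelled NOD and Rag1ko at 8 weeks asks which transcripts go with the entry of lymphocytes into the islets. The greatest rise was in Cxcl9, a chemokine induced by interferon-gamma that attracts activated T cells (log2 5.95 ± 0.34, adjusted p = 6.2e-12, 6 mice per group). Cxcl10, which binds the same receptor, rose by 3.32 ± 0.28, and the interferon-induced GTPases Iigp1 and Gbp4 rose by 3.68 ± 0.31 and 3.42 ± 0.32. Transcripts of leukocytes followed: Cd52 (3.12 ± 0.35), the T cell receptor component Cd3g (2.92 ± 0.38, adjusted p = 1.6e-05), the macrophage lysozyme Lyz2 (2.88 ± 0.40) and the chemokine Ccl5 (2.83 ± 0.40). The joining chain of secreted immunoglobulin, Jchain, rose by 4.05 ± 0.58 (adjusted p = 8.1e-05). Among the genes that fell were Rsph1 (-1.66 ± 0.11, adjusted p = 4.1e-10), Dennd4a (-1.37 ± 0.25), Sdc2 (-1.30 ± 0.11) and Slc37a1 (-1.08 ± 0.11).

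Gene groups of lymphocytes were higher in NOD than in Rag1ko islets at 8 weeks. Of 21 measured T cell genes 11 rose (16 adjusted over the list alone) and none fell, with a median of 0.60 and an adjusted p of 3.9e-16 for the group. Cd3d rose by 1.96 ± 0.35 and Thy1 by 1.84 ± 0.40. Cytotoxic effector genes gave 8 of 15 higher (8 adjusted over the list alone, median 0.44, adjusted p = 5.6e-12). Nkg7 rose by 2.26 and Xcl1 by 1.85. Of 9 NK cell genes 2 rose (3 adjusted over the list alone; adjusted p = 0.001), with Il2rb at 1.43. Among 12 regulatory and checkpoint genes 5 rose (7 adjusted over the list alone, with 1 lower), including Tigit (1.13) and Ctla4 (0.98). That group had an adjusted p of 5.6e-06, and adjusted p = 0.053 with an estimated correlation. B cell genes gave 5 of 19 higher (13 adjusted over the list alone; median 0.69, adjusted p = 7.6e-11), Cd72 by 1.09 and Bank1 by 0.97, and adjusted p = 0.083 with an estimated correlation. Of 9 plasma cell and immunoglobulin genes only Jchain passed over all genes (3 rose adjusted over the list alone; adjusted p = 0.0036, and adjusted p = 0.062 with an estimated correlation).

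Myeloid and antigen presentation genes also rose in NOD islets. Of 20 macrophage genes 16 rose (17 adjusted over the list alone; median 0.78, adjusted p = 5.8e-26). Aif1 rose by 2.05 ± 0.23 and the complement component C1qc by 1.53 ± 0.22. Batf3-dependent dendritic cell genes gave 4 of 12 higher (8 adjusted over the list alone; median 0.41, adjusted p = 1.1e-06). Ifi205 rose by 1.67, Irf8 by 0.83 and Itgae by 0.70, while Wdfy4 stood at 0.89 (adjusted p = 0.05). Of 2 surface markers of these cells, picked after their values were seen, Clec9a rose by 0.59 and Xcr1 stood at -0.16 (adjusted p = 0.66). Other dendritic cell genes gave 6 of 16 (8 adjusted over the list alone; adjusted p = 5e-08), such as the costimulatory ligand Cd86 (1.22). All 10 measured genes of MHC class II presentation rose (10 adjusted over the list alone; median 1.46, adjusted p = 3.4e-23), with the class II chains H2-Ab1 at 2.12 ± 0.25 and H2-Aa at 1.96 ± 0.21. MHC class I presentation gave 9 of 11 (11 adjusted over the list alone; median 0.73, adjusted p = 3.1e-23), with the immunoproteasome subunit Psmb9 at 1.77 and the peptide transporter Tap1 at 1.49. Neutrophil genes did not pass as a group (median -0.10, adjusted p = 0.17), and the granule protein Ngp fell by 0.47 (1 of 12, and 1 adjusted over the list alone).

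Interferon, chemokine and tissue inflammation groups were also higher in NOD islets at 8 weeks. Interferon-gamma response genes gave 11 of 13 higher (11 adjusted over the list alone; median 1.87, adjusted p = 7.8e-28), including the ubiquitin-like protein Ubd (2.39). The score of this group was 6.52 ± 0.69 in NOD and 4.57 ± 0.09 in Rag1ko (n = 6 each), a difference of 1.95 by a two-sided exact permutation test (adjusted p = 0.0067 over the 31 groups). Type I interferon response genes gave 8 of 21 (11 adjusted over the list alone; median 0.47, adjusted p = 5e-08), with Zbp1 at 1.69. Of 21 chemokine genes 10 rose (16 adjusted over the list alone; median 0.76, adjusted p = 3.6e-22). Ccl19 rose by 2.84. Of 19 cytokine genes 6 rose (7 adjusted over the list alone; median 0.20, adjusted p = 6.1e-06). Ltb rose by 1.56, Il1b by 1.14 and Ifng by 0.69 ± 0.18 (adjusted p = 0.022). Leukocyte adhesion and homing genes gave 8 of 12 (9 adjusted over the list alone; adjusted p = 1.2e-12), including Vcam1 (1.73) and the integrin chain Itgb2 (1.47). Lymphoid tissue organization genes gave 4 of 13 (6 adjusted over the list alone; adjusted p = 6.1e-08). Cxcl13 rose by 2.45. Complement genes gave 7 of 11 (9 adjusted over the list alone; median 1.13, adjusted p = 6.4e-14), including C1s1 (1.76). Lists share members, such as Cxcl9 in the interferon-gamma and chemokine lists.

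Beta cell genes, in the same comparison, had a median of -0.14 (adjusted p = 0.00049, and adjusted p = 0.28 with an estimated correlation). In this group 2 of 21 fell (2 adjusted over the list alone), the transcription factors Nkx6-1 (-0.35 ± 0.09) and Pax6 (-0.31 ± 0.09), while insulin, Ins2, named after its values were seen, stood at 0.00 ± 0.06 (adjusted p = 0.98). The score of the group was 9.57 ± 0.11 in NOD and 9.72 ± 0.04 in Rag1ko (exact permutation, adjusted p = 0.0067). Genes of other endocrine cells (median -0.05, adjusted p = 0.99) and of ER stress and the unfolded protein response (0.00, adjusted p = 0.94) did not pass. Acinar genes, markers of the exocrine tissue around the islets, moved with the immune groups. Their median was 1.25 with 1 of 25 higher, the zymogen granule protein Sycn at 2.14 ± 0.57 (13 adjusted over the list alone; adjusted p = 2.5e-11, and adjusted p = 0.16 with an estimated correlation), and their score differed by 1.15 (exact permutation, adjusted p = 0.067). Fibroblast and stellate cell genes gave 6 of 14 higher (13 adjusted over the list alone; median 0.55, adjusted p = 2.6e-14), including Dcn (2.04), Lum (1.84) and Vim (1.57).

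Of the remaining groups, endothelial genes gave 1 of 12 higher, Eng at 0.54 (3 adjusted over the list alone; adjusted p = 0.0021, and adjusted p = 0.067 with an estimated correlation). Cell cycle genes gave 1 of 17, the replication helicase subunit Mcm6 at 0.60 (1 adjusted over the list alone; median 0.34, adjusted p = 3.1e-05, and adjusted p = 0.17 with an estimated correlation). Immediate early and isolation stress genes ran the other way, with 7 of 13 lower and 2 higher in NOD (10 and 2 adjusted over the list alone; median -0.75, adjusted p = 0.00018, and adjusted p = 0.25 with an estimated correlation). Ier2 fell by 1.25, Fosb by 1.11 and Fos by 0.92. Duct (median 0.01, adjusted p = 0.40), Reg family (-0.12, adjusted p = 0.56), adipocyte (median -0.11 and mean 0.01, adjusted p = 0.93) and Schwann cell genes (median 0.06 and mean -0.02, adjusted p = 0.97) did not pass, and in the last 2 groups the test took the lower direction.

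In all, 812 genes differed between NOD and Rag1ko islets at 8 weeks, 565 higher and 247 lower in NOD. The values of the 6 and 6 mice did not overlap for 298 of them, and of all genes tested for 2.16%, where chance parts 0.216%. Of the 31 gene groups 24 were called, 22 higher and 2 lower, and 16 of these hold with an estimated correlation. The count was 481 without NOD mouse 5, 473 without NOD mouse 6, 317 with only these 2 groups in the fit and 173 with mice 1 to 3 of each group. The call of the regulatory group ended when dim genes were left out (adjusted p = 0.083; range over its alternatives 1.5e-07 to 0.083).

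**Figure D1:**
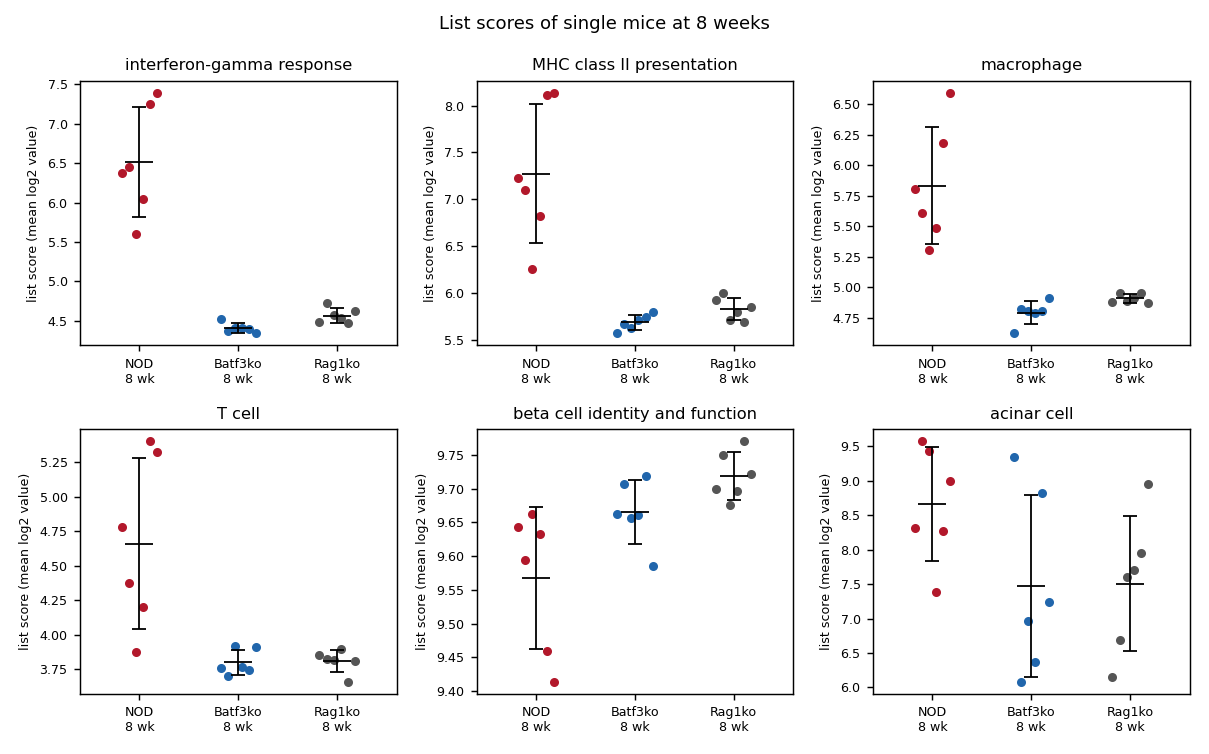
Mean log2 value of the listed genes in each mouse at 8 weeks (y axis, log2 units) for NOD, Batf3ko and Rag1ko islets, with 1 point per mouse (6 per group) and the group mean ± SD. In the interferon-gamma panel the NOD mice lie between 5.6 and 7.39, above every mouse of the other groups.

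The comparison of islets labelled Batf3ko and NOD at 8 weeks asks what islet inflammation looks like without Batf3. The genes that led the previous comparison fell here. Cxcl9 was lower in Batf3ko islets by a log2 of -5.90 ± 0.34 (adjusted p = 7.7e-12, 6 mice per group), Jchain by -4.13 ± 0.58 (ended with mice 1 to 3, adjusted p = 0.051; range 4.2e-09 to 0.051), Iigp1 by -3.90 ± 0.31, Cxcl10 by -3.89 ± 0.28 and Gbp4 by -3.36 ± 0.32. Lyz2 (-3.20), Ccl5 (-2.92), Cd52 (-2.90) and the leukocyte actin-bundling protein Lcp1 (-2.89) fell as well. The rises were smaller and of other kinds of genes: the transcription factor Zbtb16 (1.28 ± 0.20, adjusted p = 0.00015), the glucocorticoid-inducible co-chaperone Fkbp5 (1.08 ± 0.15), the sulfotransferase Sult1d1 (0.99), the transcription factor Sox4 (0.97) and the clock repressor Cry2 (0.93).

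Lymphocyte groups were lower in Batf3ko than in NOD islets. Of 21 T cell genes 13 fell (15 adjusted over the list alone; median -0.61, adjusted p = 2.6e-14), with Cd3g at -2.75 ± 0.38 and Thy1 at -2.07. The T cell score was 3.80 ± 0.09 in Batf3ko, 4.66 ± 0.62 in NOD and 3.81 ± 0.08 in Rag1ko, and the difference between Batf3ko and NOD passed an exact permutation test (adjusted p = 0.013). Cytotoxic effector genes gave 8 of 15 lower (9 adjusted over the list alone; adjusted p = 2.5e-10), Nkg7 by -2.21. Regulatory and checkpoint genes gave 6 of 12 (8 adjusted over the list alone, with 1 higher; adjusted p = 2.9e-07), Ctla4 by -1.29, and NK cell genes 3 of 9 (3 adjusted over the list alone; adjusted p = 0.00043), Il2rb by -1.48. B cell genes gave 3 of 19 (12 adjusted over the list alone; median -0.60, adjusted p = 4.6e-08, and adjusted p = 0.15 with an estimated correlation), including Ms4a1, the B cell antigen CD20, at -1.10 (adjusted p = 0.043). The B cell score differed by -0.54, which did not pass the exact permutation test (adjusted p = 0.14). Plasma cell and immunoglobulin genes gave 1 of 9, Jchain (2 lower and 1 higher adjusted over the list alone; adjusted p = 0.0088, and adjusted p = 0.091 with an estimated correlation).

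Batf3-dependent dendritic cell genes were lower in Batf3ko than in NOD for 5 of 12 (6 adjusted over the list alone, median -0.37, adjusted p = 1.3e-05). Ifi205 fell by 1.57, Wdfy4 by 1.13, Irf8 by 1.07 and Itgae by 0.66. Clec9a (-0.43, adjusted p = 0.057) and Xcr1 (-0.12, adjusted p = 0.70), picked after their values were seen, did not pass. The score of this group differed by -0.48 (exact permutation, adjusted p = 0.0052). Other dendritic cell genes gave 7 of 16 lower (9 adjusted over the list alone; median -0.58, adjusted p = 7.1e-09), Cd86 by -1.31, and macrophage genes 16 of 20 (18 adjusted over the list alone; median -0.96, adjusted p = 1.5e-25), Aif1 by -2.26 and C1qc by -1.95. MHC class II presentation fell in 9 of 10 (10 adjusted over the list alone; median -1.54, adjusted p = 1.2e-20), Cd74 by -2.69 ± 0.23, and MHC class I presentation in 9 of 11 (10 adjusted over the list alone; median -0.67, adjusted p = 7.9e-19), B2m by -1.82 ± 0.16. Neutrophil genes did not pass (median 0.03 and mean -0.03, tested toward lower, adjusted p = 0.98), and 1 of 12, Lcn2, fell by 0.96 (1 adjusted over the list alone).

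Interferon-gamma response genes fell in 11 of 13 (11 adjusted over the list alone; median -2.12, adjusted p = 4e-26), Ubd by -2.70, and the score of Batf3ko islets was 4.41 ± 0.06 against 6.52 ± 0.69 in NOD (exact permutation, adjusted p = 0.0052). Type I interferon response genes gave 12 of 21 lower (15 adjusted over the list alone; median -0.74, adjusted p = 5e-16), Ifi27l2a by -1.89 and Rtp4 by -1.55. Chemokines gave 12 of 21 (15 adjusted over the list alone; median -0.94, adjusted p = 1.9e-19), Ccl19 by -2.93. Cytokines gave 6 of 19 (8 adjusted over the list alone; adjusted p = 1.1e-05), Il1b by -1.36 and Ifng by -0.66 (adjusted p = 0.02). Adhesion and homing genes gave 7 of 12 (9 adjusted over the list alone; adjusted p = 4.1e-10), Vcam1 by -1.76, and complement genes 8 of 11 (10 adjusted over the list alone; median -1.25, adjusted p = 8.7e-15), C1s1 by -1.79. Lymphoid tissue organization gave 4 of 13 (7 adjusted over the list alone; adjusted p = 6.6e-07, and adjusted p = 0.055 with an estimated correlation), Cxcl13 by -2.47.

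Among the tissue groups, fibroblast and stellate cell genes fell in 8 of 14 (11 adjusted over the list alone; median -0.58, adjusted p = 5.9e-12), Dcn by -1.89 and Vim by -1.68. Acinar genes again moved with the immune groups, with a median of -1.30 and 1 of 25 lower, the transcription factor Bhlha15 at -0.61, named after its values were seen (23 adjusted over the list alone; adjusted p = 7.9e-11, and adjusted p = 0.17 with an estimated correlation). Their score was 7.47 ± 1.33 in Batf3ko, 8.66 ± 0.83 in NOD and 7.51 ± 0.98 in Rag1ko (Batf3ko against NOD, exact permutation, adjusted p = 0.14). Genes of ER stress and the unfolded protein response fell in 5 of 19 and rose in 1 (10 and 1 adjusted over the list alone; median -0.22, adjusted p = 5.2e-05, and adjusted p = 0.11 with an estimated correlation). Dnajb11 and Dnajb9 fell by 0.54 and 0.46, while Chac1 rose by 0.67. Cell cycle genes fell in 2 of 17 (2 adjusted over the list alone; median -0.23, adjusted p = 0.00062, and adjusted p = 0.28 with an estimated correlation), Top2a by 0.94. Beta cell genes did not pass as a group (median 0.04, adjusted p = 0.12), and 1 of 21, the islet transcription factor Rfx6, rose by 0.49 (1 adjusted over the list alone). The beta cell group was called with quantile normalization (mean 0.13, adjusted p = 0.010) and without dim genes (0.10, adjusted p = 0.035), where the adjusted p ran from 0.010 to 0.67 over its alternatives.

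Groups of other endocrine cells (median 0.03, adjusted p = 0.85; Ttr higher by 0.27), adipocytes (0.12, adjusted p = 0.45; Car3 higher by 0.48), duct (-0.16, adjusted p = 0.41), Reg family (-0.04, adjusted p = 0.56) and Schwann cells (-0.03, adjusted p = 0.82) did not pass. Endothelial genes went both ways (1 of 12 higher, Cldn5 at 0.36, and 2 lower, Eng and Kdr; adjusted p = 0.13). Immediate early and isolation stress genes had none of 13 past the test (median 0.21, mean 0.08, tested toward lower, adjusted p = 0.98). In all, 1527 genes differed, 645 higher and 882 lower in Batf3ko, and for 542 the arrays of the groups did not overlap (3.3% of all genes tested, chance 0.216%). Of the 31 groups 22 were called, all lower, and 16 hold with an estimated correlation. The count was 912 with the acinar score as a covariate, 757 with only these 2 groups in the fit and 428 with mice 1 to 3, and the call of the B cell group ended without dim genes (adjusted p = 0.23; range over its alternatives 5.5e-11 to 0.23).

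**Figure D2:**
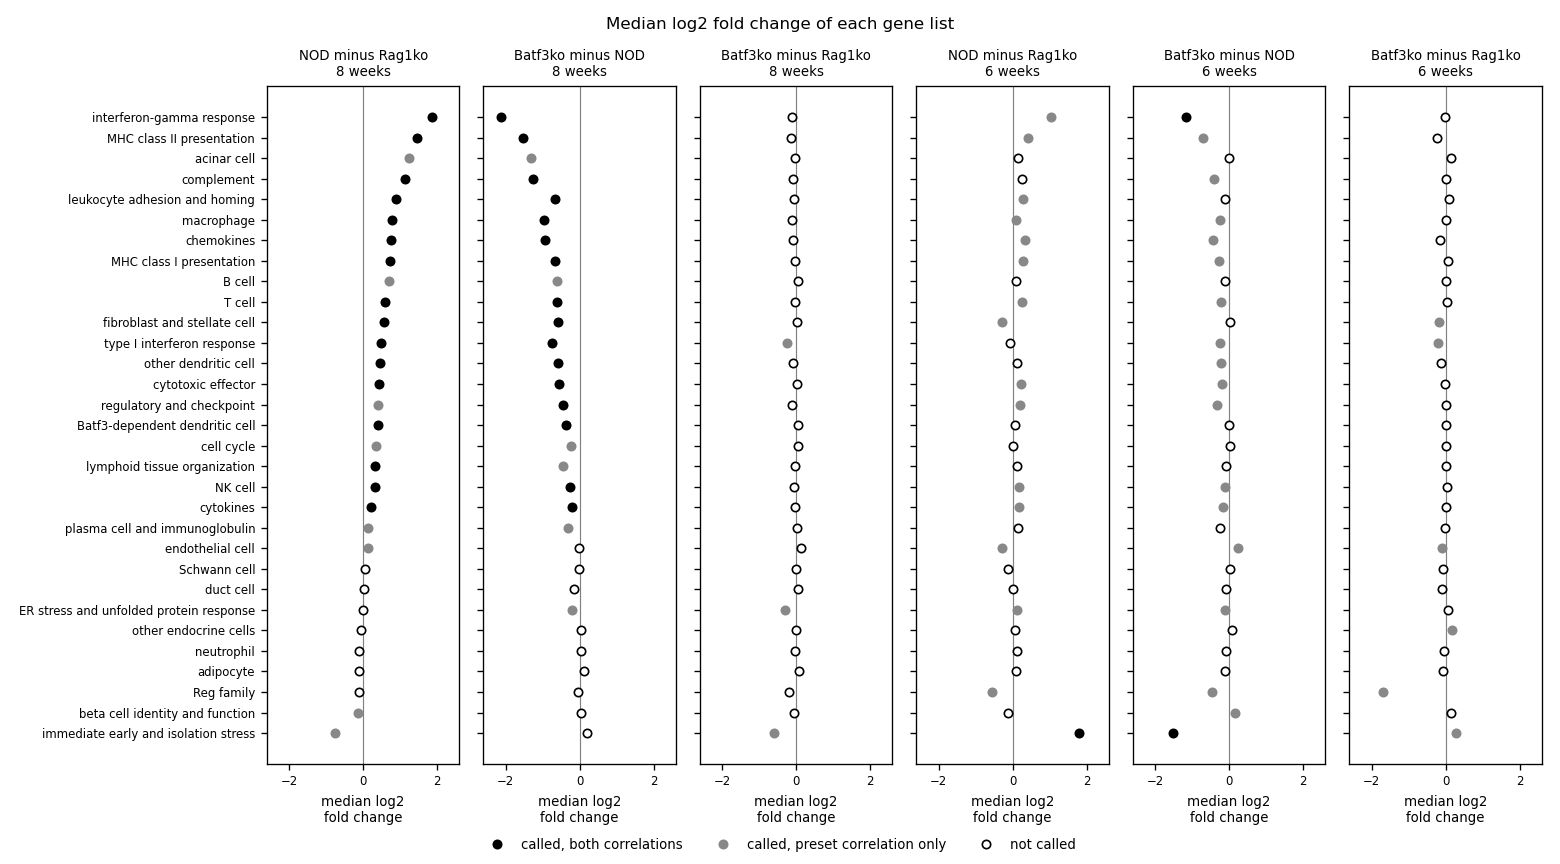
Median log2 difference of each of the 31 gene groups (x axis, log2 units) in the 3 comparisons at 8 weeks and the 3 at 6 weeks, with 1 line per group. Points are black where the call holds with both correlations, grey where it holds with the preset one only and open where there was no call, and at 8 weeks the interferon-gamma group lies at 1.87 for NOD minus Rag1ko, -2.12 for Batf3ko minus NOD and -0.12 for Batf3ko minus Rag1ko.

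The comparison of islets labelled Batf3ko and Rag1ko at 8 weeks asks whether islets without Batf3 differ from those of mice without mature lymphocytes. The leading inflammatory genes did not pass this test: Cxcl9 stood at 0.05 ± 0.34 (adjusted p = 0.98, 6 mice per group), Cxcl10 at -0.57 ± 0.28 (adjusted p = 0.46), Jchain at -0.08 ± 0.58 (adjusted p = 0.98) and Cd3g at 0.17 ± 0.38 (adjusted p = 0.92). These SEs pool all groups, and NOD mice spread most (interferon-gamma score SD 0.69 against 0.06 and 0.09). Pooling weakens these tests, and it makes the SEs of the 8-week comparisons with NOD likely too small for such genes. Cxcl9 and Jchain are named for their place in the other comparisons. Genes that did differ included circadian transcription factors that rose in Batf3ko, Dbp (0.89 ± 0.15, adjusted p = 0.0023), Hlf (0.72) and Nr1d2 (0.57). The adhesion receptor Cd44, which lies on the chromosome of Rag1, was higher by 0.70 ± 0.10 (adjusted p = 0.00038), and Vaultrc5 and Fam107a by 1.21 and 0.81. Lancl1 and the mitochondrial fatty acid enzyme Acadl, both on the chromosome of Batf3, were higher by 0.69 and 0.62. Rsph1 (-1.88 ± 0.11, adjusted p = 4.3e-11), Sdc2 (-1.15 ± 0.11), Scd1 (-1.03) and Socs3 (-1.01) were lower in Batf3ko. With mice 1 to 3 the calls of Hlf, Nr1d2, Fam107a, Lancl1, Acadl and Socs3 ended (adjusted p = 0.15, 0.15, 0.23, 0.18, 0.17 and 0.21, each the highest over the alternatives of its gene; lowest 0.0012, 0.0083, 0.00071, 0.00083, 0.0035 and 0.00071).

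Of the 31 gene groups 3 were called between Batf3ko and Rag1ko at 8 weeks, all lower in Batf3ko, and none of them holds with an estimated correlation. Type I interferon response genes had none of 21 past the test over all genes (7 lower adjusted over the list alone; median -0.25, adjusted p = 7e-06, and adjusted p = 0.58 with an estimated correlation). Genes of ER stress and the unfolded protein response fell in 3 of 19 (10 lower and 1 higher adjusted over the list alone; median -0.29, adjusted p = 1.8e-07, and adjusted p = 0.41 with an estimated correlation), Pdia4 by 0.41. Immediate early and isolation stress genes fell in 3 of 13 and rose in 1 (8 and 2 adjusted over the list alone; median -0.60, adjusted p = 7e-06, and adjusted p = 0.74 with an estimated correlation), Junb by 0.89 against a rise of the heat shock protein Hspb1 by 0.80. None of the other 28 groups passed (smallest adjusted p = 0.23). In this comparison the median, the mean and the test differed in sign for the plasma cell, Batf3-dependent dendritic cell, MHC class I, adhesion, other endocrine and duct groups, all with medians between -0.06 and 0.06.

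A missed threshold does not show that the groups were alike, so score differences are given with 95% intervals of the exact permutation test, unadjusted. The T cell score differed by -0.01 (interval -0.11 to 0.09), the cytotoxic score by 0.02 (-0.08 to 0.11) and the Batf3-dependent dendritic cell score by -0.01 (-0.08 to 0.06). The B cell score was higher by 0.07 (0.01 to 0.14), and lower were the macrophage (-0.12, -0.20 to -0.04), regulatory (-0.09, -0.13 to -0.04), complement (-0.12, -0.22 to -0.03), beta cell (-0.05, -0.11 to -0.01) and ER stress scores (-0.19, -0.34 to -0.05). The MHC class II score differed by -0.14 (-0.27 to -0.01), the interferon-gamma score by -0.16 (-0.26 to -0.07) and the type I interferon score by -0.28 (-0.41 to -0.15). The acinar score left a wide interval (-0.04, -1.60 to 1.47). Adjusted over the 31 groups 0 scores passed the exact permutation test (smallest adjusted p = 0.067), and 3 passed without Batf3ko mouse 1. Here 1 score alone at the smallest p (0.0022) cannot pass. Type I interferon was at it, with mice that did not overlap.

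In all, 101 genes differed between Batf3ko and Rag1ko islets, 38 higher and 63 lower in Batf3ko, and the groups did not overlap for 67 of them (1.09% of all genes tested, chance 0.216%). At an unadjusted p under 0.05 there were 2201. Leaving out 1 mouse gave 60 to 113 genes, with 63, 64 and 61 without Batf3ko mice 1, 3 and 5 and 60 and 67 without Rag1ko mice 3 and 6. The fit of these 2 groups alone gave 46 genes, that of the 8-week arrays alone, added after the data were seen, 52, and mice 1 to 3 gave 15.

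The comparisons of NOD with either knockout share the NOD arrays. Of the 812 and 1527 genes, 530 were called in both with the knockouts on the same side of NOD, 444 higher and 86 lower in NOD, and 1 was called with the knockouts on opposite sides. Independent lists of these sizes would share 25 and 8 genes. In 50 simulations of 3 unchanged groups that share their NOD arrays the mean and highest count were 0, but without an effect almost nothing is called, so this does not show how far the shared arrays raise the 530. With NOD mice 1 to 3 used against Rag1ko and 4 to 6 against Batf3ko the count was 102 (88 and 14, where independent lists give 5.3 and 1), and with the mice exchanged 155 (140 and 15, independent lists 12 and 2.1). Across genes, which are not independent replicates, the log2 differences correlated at -0.83 with a covariance of -0.0604, against -0.50 and -0.0075 in the simulations. Split NOD arrays gave correlations of -0.58 and -0.54 and covariances of -0.0468 and -0.0454.

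Of the 565 genes higher in NOD than in Rag1ko at 8 weeks, 10 differed between Batf3ko and Rag1ko, 9 of them toward NOD. Their median was 0.74 for NOD minus Rag1ko and 0.02 for Batf3ko minus Rag1ko. Of the 247 genes lower in NOD, 21 differed between Batf3ko and Rag1ko, all 21 toward NOD, and the medians were -0.39 and -0.15. Both comparisons use the same Rag1ko arrays, so that a shared sign is partly built in, and these counts were not compared with chance.

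**Figure D3:**
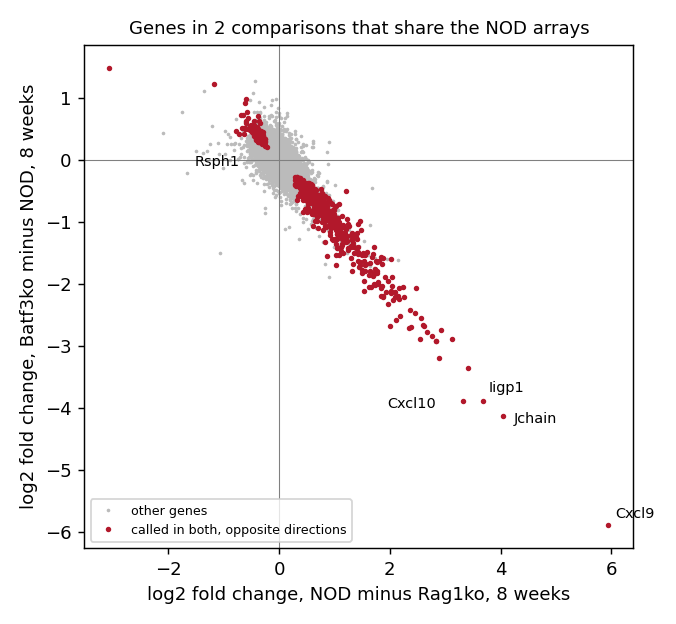
Log2 difference NOD minus Rag1ko (x axis) against Batf3ko minus NOD (y axis) at 8 weeks, with 1 point per gene and the 530 genes called in both comparisons in colour. Cxcl9 lies farthest out at 5.95 and -5.90, and the isolated point at the left is the microRNA gene Mir7b (-3.07 and 1.49), which falls outside the naming rule and was picked after its values were seen.

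The comparison of NOD with Rag1ko at 6 weeks asks the same question at an earlier age. Cxcl9 was already higher in NOD islets (log2 4.23 ± 0.47, adjusted p = 2.2e-06, 3 mice per group), as were Iigp1 (3.05 ± 0.43) and Cxcl10 (2.80 ± 0.40). The stress-induced transcription factors Atf3 (3.25 ± 0.48) and Fosb (3.09 ± 0.40) and the gene Fam71a (3.42 ± 0.27) rose with them. Reg3g, a secreted lectin of the exocrine pancreas and gut, was lower in NOD by -4.61 ± 0.45 (adjusted p = 4.2e-07), the clock activator Arntl by -1.90 ± 0.24, Dennd4a by -2.09 ± 0.35 and Lgals9 by -1.69 ± 0.31. The complement gene C4b fell by 1.71 (adjusted p = 0.041), a call that ended without Rag1ko mouse 1 (adjusted p = 0.24; range over its alternatives 0.012 to 0.24). That of Lgals9 ended with only these 2 groups in the fit (adjusted p = 0.15; range 0.00036 to 0.15).

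Of the 31 groups 16 were called between NOD and Rag1ko at 6 weeks, and only the immediate early and isolation stress group holds with an estimated correlation. All 13 of its genes rose (13 adjusted over the list alone; median 1.78, adjusted p = 2e-32, and adjusted p = 0.010 with an estimated correlation). Nr4a1 rose by 2.28 and the phosphatase Dusp1 by 2.08. Its score was 10.06 ± 0.02 in NOD, 8.46 ± 0.52 in Batf3ko and 8.15 ± 0.34 in Rag1ko, n = 3 each. Beside it, interferon-gamma response genes rose in 6 of 13 (8 adjusted over the list alone; median 1.03, adjusted p = 1.6e-11, and adjusted p = 0.099 with an estimated correlation). Chemokines rose in 5 of 21 (8 higher and 1 lower adjusted over the list alone; adjusted p = 4.8e-07, and adjusted p = 0.28 with an estimated correlation). Cxcl2 rose by 2.40. MHC class I gave 2 of 11 (4 adjusted over the list alone; adjusted p = 7.6e-05, and adjusted p = 0.35 with an estimated correlation) and MHC class II 2 of 10 (3 adjusted over the list alone; adjusted p = 0.0022, and adjusted p = 0.53 with an estimated correlation). H2-Ab1 rose by 1.45 and Cd74 by 1.44. ER stress genes gave 4 of 19 (6 adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.40 with an estimated correlation). Ddit3 rose by 1.59 and Chac1 by 1.76.

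The groups of T cells (adjusted p = 0.024, none of 21 genes past the test), cytotoxic effectors (0.014), regulatory genes (0.026, with Ctla4 at 1.31), NK cells (0.025), macrophages (0.025), cytokines (0.021, with Tnf at 1.11) and adhesion (0.047, with Cd44 at 0.56) were also called higher in NOD at 6 weeks. With an estimated correlation their adjusted p ran from 0.29 to 0.60. Groups called lower were endothelial (median -0.29, 1 of 12 genes, Emcn at -0.84; adjusted p = 0.00012, and adjusted p = 0.099 with an estimated correlation), Reg family (median -0.57, 1 of 7; adjusted p = 0.025, and adjusted p = 0.53 with an estimated correlation) and fibroblast (median -0.29, 0 of 14; adjusted p = 0.026, and adjusted p = 0.60 with an estimated correlation), the last lost without Rag1ko mouse 1 (adjusted p = 0.66; range over its alternatives 0.00049 to 0.66). The other 15 groups did not pass. Acinar genes were at a median of 0.15 (adjusted p = 0.70), Batf3-dependent dendritic cell genes at 0.07 (adjusted p = 0.40), type I interferon genes at -0.07 (adjusted p = 0.82) and beta cell genes at -0.12 (adjusted p = 0.20), while adipocyte genes differed in sign between median (0.10) and mean (-0.02).

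In all, 772 genes differed between NOD and Rag1ko at 6 weeks, 287 higher and 485 lower in NOD, or 324 and 353 with quantile normalization across the arrays. Arrays did not overlap for 744 of them, and over all genes tested for 20.3%, where chance parts 10%. For list scores 3 mice against 3 cannot give an exact permutation p below 0.10. The count was 377 without NOD mouse 2, 500 and 477 without Rag1ko mice 2 and 3, 197 with only these 2 groups in the fit, 476 with the 6-week arrays alone, added after the data were seen, and 1965 with array weights.

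The comparison of Batf3ko with NOD at 6 weeks asks whether the loss of Batf3 is visible early. Cxcl9 (log2 -4.54 ± 0.47, adjusted p = 2.9e-06, 3 mice per group), Iigp1 (-3.07 ± 0.43), Cxcl10 (-2.94 ± 0.40), Fam71a (-3.27 ± 0.27) and Atf3 (-2.91 ± 0.48) were lower in Batf3ko islets. The highest genes were Zfp617 (1.27), the synaptotagmin Syt11 (1.19) and the deubiquitinase Usp46 (1.03). With only these 2 groups in the fit the calls of Atf3, Syt11 and Usp46 ended (adjusted p = 0.11, 0.16 and 0.099, the highest over their alternatives; lowest 0.00011, 0.00017 and 0.00054). All 13 immediate early genes fell (13 adjusted over the list alone; median -1.52, adjusted p = 6.2e-33), Nr4a1 by -2.25 and the heat shock gene Hspa1a by -1.87, and interferon-gamma response genes fell in 6 of 13 (9 adjusted over the list alone; median -1.16, adjusted p = 3.1e-16). These 2 groups hold with an estimated correlation. Chemokines fell in 5 of 21 (7 adjusted over the list alone; adjusted p = 3.3e-12, and adjusted p = 0.075 with an estimated correlation) and MHC class II genes in 4 of 10 (5 adjusted over the list alone; adjusted p = 6.4e-07, and adjusted p = 0.26 with an estimated correlation), Cd74 by -1.83. MHC class I (1 of 11, B2m at -1.40), ER stress (2 of 19, Ddit3 at -1.16), regulatory (1 of 12, Ctla4 at -1.13) and cytokine genes (1 of 19, Tnf at -1.05) were called lower with adjusted p between 9.2e-05 and 0.0058, and with an estimated correlation at 0.22 or 0.26.

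The 8 further groups called lower in Batf3ko at 6 weeks had no gene past the test over all genes. They were type I interferon (adjusted p = 0.0004), cytotoxic (0.0014), complement (0.0035), T cell (0.0058), macrophage (0.0058), Reg family (0.02), NK cell (0.044) and other dendritic cell genes (0.045), and with an estimated correlation their adjusted p ran from 0.26 to 0.49. Beta cell (median 0.16, adjusted p = 0.00072, and adjusted p = 0.41 with an estimated correlation) and endothelial genes (median 0.24, adjusted p = 0.0096, and adjusted p = 0.26 with an estimated correlation) were called higher. Batf3-dependent dendritic cell genes (median 0.00, 0 of 12, adjusted p = 0.75) and acinar genes (median 0.00, adjusted p = 0.71) did not pass. In all, 194 genes differed, 59 higher and 135 lower in Batf3ko, or 40 and 156 with quantile normalization, and 192 did not overlap between the groups (16% of all genes tested, chance 10%). The count was 99 without NOD mouse 2, 308, 76 and 63 without Batf3ko mice 1, 2 and 3, 39 with only these 2 groups in the fit and 495 with array weights, and the call of Zfp617 ended without NOD mouse 2 (adjusted p = 0.26; range over its alternatives 0.0087 to 0.26).

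Batf3ko and Rag1ko were compared at 6 weeks as at 8 weeks. Clock output genes and repressors were higher in Batf3ko, Nr1d1 by 1.68 ± 0.21 (adjusted p = 0.00015, 3 mice per group), Dbp by 1.63 ± 0.21, Per3 by 1.46 ± 0.25, Nr1d2 by 1.25 ± 0.17 and Tef by 1.07 ± 0.16, while the clock activator Arntl was lower by -1.75 ± 0.24. The hour at which islets were taken is not given in the sources used here. Reg3g (-4.86 ± 0.45, adjusted p = 8.1e-07) and Reg3a (-4.73 ± 0.90, adjusted p = 0.012) were lower as well, and Cd44 was higher by 0.73 ± 0.14. The Reg family was called lower (2 of 7, and 3 adjusted over the list alone; median -1.68, adjusted p = 5.7e-08, and adjusted p = 0.16 with an estimated correlation). Type I interferon genes (median -0.22, 0 of 21, and 3 lower adjusted over the list alone; adjusted p = 1.1e-05, and adjusted p = 0.42 with an estimated correlation), endothelial (adjusted p = 0.048) and fibroblast genes (0.031) were called lower, and other endocrine (0.025) and immediate early genes (0.012) higher, the last 4 with no gene past the test and with adjusted p of 0.42 or more with an estimated correlation. The other 25 groups did not pass (smallest adjusted p = 0.061, for beta cell genes). Median, mean and test differed in sign for the regulatory, plasma cell, macrophage, lymphoid tissue, complement, cell cycle and T cell groups, with medians between -0.01 and 0.03.

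In all, 70 genes differed between Batf3ko and Rag1ko at 6 weeks, 35 higher and 35 lower, and all 70 did not overlap between the groups (11.7% of all genes tested, chance 10%). With only these 2 groups in the fit 2 genes passed, and among those that did not were Reg3g (adjusted p = 0.18), Nr1d1 (0.072), Dbp (0.18) and Arntl (0.35), each the highest p over the alternatives of its gene (lowest 3.7e-08, 3.2e-06, 4.9e-06 and 2.1e-05). The count was 8 with the 6-week arrays alone, added after the data were seen, 39 and 33 without Batf3ko mice 2 and 3, 36 without Rag1ko mouse 2, 448 with array weights and 117 when every probe set was tested. Between the ages, 30 genes were higher and 11 lower in NOD than in Rag1ko at both (independent lists give 8.1 and 6), 20 were lower at 8 weeks and higher at 6 (3.6), and 10 were higher at 8 weeks and lower at 6 (13.7). For Batf3ko minus NOD 24 were lower and 3 higher at both ages (6 and 1.9), 6 were higher at 8 weeks and lower at 6 (4.4) and 1 the other way (2.6), and for Batf3ko minus Rag1ko 6 were lower and 8 higher (0.1 each).

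**Figure D4:**
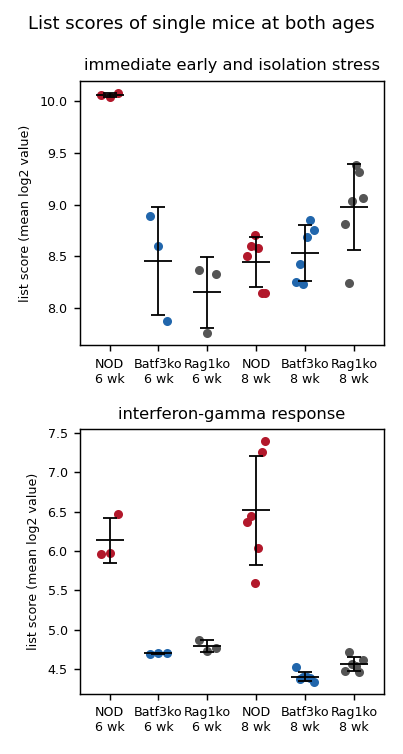
Mean log2 value of the immediate early and interferon-gamma genes in each of the 27 mice (y axis, log2 units) by genotype and age, with 1 point per mouse and the group mean ± SD. The deposited values of the 2 ages follow different distributions; at 6 weeks the immediate early score of the NOD mice lies between 10.04 and 10.08, and that of the knockouts at 8.46 ± 0.52 and 8.15 ± 0.34.

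Differences between 8 and 6 weeks were computed within each genotype to ask what changes with age, but age and the normalization of the arrays cannot be told apart here. The median of all genes shifted by -0.269 in NOD, -0.249 in Batf3ko and -0.254 in Rag1ko, and with quantile normalization across the 27 arrays by 0.025, 0.035 and 0.038. A change near the size of that shift cannot be separated from the scaling. Acinar genes fell in 25 of 25 in every genotype, with medians of -3.64 in NOD, -5.06 in Batf3ko and -4.78 in Rag1ko (adjusted p = 3.4e-06, 1.9e-14 and 9e-13, and with an estimated correlation 0.36, 0.68 and 0.60). With quantile normalization the medians were -3.29, -4.51 and -4.56, and 25 of 25 fell in each. Reg family genes fell in 7 of 7 in every genotype (medians -4.91, -3.72 and -6.28, adjusted p = 0.0012, 0.0045 and 7.6e-05, and with an estimated correlation 0.36, 0.68 and 0.33), or in 6 of 7 with quantile normalization. Duct genes fell in 8, 6 and 6 of 8 (medians -1.14, -1.06 and -1.16, adjusted p = 0.0022, 0.0038 and 0.013, and with an estimated correlation 0.36, 0.44 and 0.33). With quantile normalization 5, 5 and 4 of them fell (medians -0.80, -0.75 and -0.86). The exocrine secretory protein Serpini2 fell by 6.17, 6.81 and 7.18 (SE 0.50 each).

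In NOD islets Cd3g rose with age by 2.29 ± 0.46 (adjusted p = 0.00016, 6 mice against 3), Jchain by 3.38 ± 0.72, Plac8 by 2.42 ± 0.43, Thy1 by 2.15 ± 0.49, the B cell attractant Cxcl13 by 2.11 ± 0.54 and the neuropeptide Vip by 2.97 ± 0.70. With the acinar score as a covariate the calls of Thy1 (adjusted p = 0.20), Cxcl13 (0.11) and Vip (0.15) ended, each the highest p over the alternatives of its gene (lowest 3.8e-05, 0.00018 and 2.6e-05). Groups called higher with age in NOD were T cell (7 of 21 higher and 3 lower, median 0.23, adjusted p = 0.00049), macrophage (9 and 5 of 20, 0.30, 0.0003), MHC class II (3 of 10, 0.55, 0.0003) and chemokine genes (7 and 2 of 21, 0.53, 0.0003), with adjusted p = 0.36 with an estimated correlation in each. With quantile normalization the genes higher and lower were 14 and 0, 10 and 1, 5 and 0, and 10 and 1, and the medians 0.74, 0.60, 0.70 and 0.77. Also called higher were the MHC class I, fibroblast, both dendritic cell, complement, B cell, interferon-gamma, type I interferon, adhesion and lymphoid tissue groups (adjusted p from 0.00038 to 0.045, and with an estimated correlation from 0.36 to 0.45). With quantile normalization the calls of the interferon-gamma (adjusted p = 0.077) and lymphoid tissue groups (0.13) ended. Calls of the cytotoxic (0.011), cytokine (0.0082) and beta cell groups (0.015) appeared. ER stress genes fell in 12 of 19 and rose in 2 (adjusted p = 0.006, and adjusted p = 0.36 with an estimated correlation), and immediate early genes fell in 12 of 13 and rose in 1 (median -1.73, adjusted p = 0.0018, and adjusted p = 0.38 with an estimated correlation).

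In Batf3ko islets the heat shock gene Hspa1a rose with age by 2.45 ± 0.15, Vaultrc5 by 2.15 and the activity-induced transcription factor Npas4 by 1.64, a call that ended with the acinar covariate (adjusted p = 0.08; range 0.00059 to 0.08). In Rag1ko islets Fosb rose by 2.21 ± 0.34, Hspa1a by 2.14 ± 0.15 and Dnajb1 by 1.30. In Batf3ko ER stress genes fell in 15 of 19 (median -0.63, adjusted p = 0.00093, and adjusted p = 0.68 with an estimated correlation), and the immediate early group (median -0.19, mean 0.08) and the chemokines (median -0.22) were called higher relative to all other genes (adjusted p = 0.026 and 0.014, and adjusted p = 0.98 with an estimated correlation). In Rag1ko immediate early genes rose in 7 of 13 and fell in 1 (median 0.62, adjusted p = 1.1e-09, and adjusted p = 0.33 with an estimated correlation) and cell cycle genes fell in 15 of 17 (median -0.74, adjusted p = 0.025, and adjusted p = 0.98 with an estimated correlation). With quantile normalization cell cycle genes fell in 9 of 17 (median -0.39), and in Batf3ko ER stress genes fell in 10 and rose in 1 (median -0.33). Chemokines (median -0.08, adjusted p = 0.036) and beta cell genes (median -0.02, mean 0.02, adjusted p = 0.013) were called higher relative to other genes, with adjusted p = 0.98 with an estimated correlation. The test compares a group with all other genes, most of which had lower values at 8 weeks, so that a group can be called higher with a median below 0. Medians near 0 turned sign with quantile normalization, to 0.03 for immediate early genes and 0.14 for chemokines in Batf3ko and to 0.28 for chemokines and 0.43 for beta cell genes in Rag1ko. With that scaling the calls of immediate early genes (adjusted p = 0.74) and chemokines (0.30) in Batf3ko and of chemokines in Rag1ko (0.28) ended, and that of beta cell genes in Rag1ko did not (1.8e-05). In Batf3ko beta cell genes were then called higher (0.021) and cell cycle genes lower (0.0057).

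In all, 10886 genes differed between the ages in NOD (1602 higher and 9284 lower at 8 weeks), 9192 in Batf3ko (867 and 8325) and 9547 in Rag1ko (970 and 8577). With quantile normalization the counts were 3996 and 3527, 3430 and 2781, and 3633 and 2942, so the split between higher and lower follows the scaling. Arrays did not overlap for 8743, 7296 and 7832 of the genes (46.1%, 40.5% and 43.3% of all genes tested, chance 2.38%). With the acinar score as a covariate 6702, 2754 and 3387 genes differed.

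The interactions ask whether a genotype difference changed between the ages, and they are open to the same limits of normalization and exocrine tissue. For NOD minus Rag1ko 726 genes passed, 422 with a positive and 304 with a negative value, or 291 and 334 with quantile normalization. The sign gives the direction of the change, not whether the difference grew: Reg3g, lower in NOD at 6 weeks, had means of 2.64 in NOD and 2.76 in Rag1ko at 8 weeks. Reg3g (4.49 ± 0.56) and the matrix proteins Lum (2.73 ± 0.63) and Dpt (2.86 ± 0.80) led one side, and Atf3 (-4.20 ± 0.59), Fosb (-4.20 ± 0.49) and Polg2 (-3.83 ± 0.35) the other. The call of Dpt ended under several alternatives (adjusted p from 0.0095 to 0.26). Immediate early genes passed with a negative value in 12 of 13 (12 adjusted over the list alone, median -2.48, adjusted p = 9.5e-27, and adjusted p = 0.027 with an estimated correlation). Endothelial genes passed with a positive value in 2 of 12 (5 adjusted over the list alone, median 0.34, adjusted p = 4.2e-06, and adjusted p = 0.038 with an estimated correlation) and fibroblast genes in 7 of 14 (10 adjusted over the list alone, adjusted p = 2.8e-09, and adjusted p = 0.30 with an estimated correlation). Acinar genes moved with them (median 1.10, 0 of 25, adjusted p = 0.00097, and adjusted p = 0.53 with an estimated correlation). The count was 393 without NOD mouse 2 of 6 weeks, 360 with mice 1 to 3 and 1318 with array weights, and the call of Lum ended without Rag1ko mouse 1 of 6 weeks (adjusted p = 0.067; range over its alternatives 0.0034 to 0.15). Of the 31 groups 20 were called, and 2 of these hold with an estimated correlation.

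For Batf3ko minus NOD 377 genes passed, 209 with a positive and 168 with a negative value, or 200 and 83 with quantile normalization. Npas4 (3.33 ± 0.57), Atf3 (3.16 ± 0.59), Rgs2 (2.78 ± 0.55) and Gem (2.78 ± 0.36) were positive and the leukocyte genes Lcp1 (-2.70 ± 0.55) and Plac8 (-2.64 ± 0.60) negative. With mice 1 to 3 the calls of Atf3, Rgs2, Lcp1 and Plac8 ended (ranges over their alternatives 0.0016 to 0.05, 8.3e-05 to 0.056, 0.00037 to 0.074 and 0.0048 to 0.093). Immediate early genes rose in 12 of 13 (12 adjusted over the list alone; median 1.54, adjusted p = 1.6e-17, and adjusted p = 0.15 with an estimated correlation) and macrophage genes fell in 2 of 20 (8 adjusted over the list alone; median -0.65, adjusted p = 3e-08, and adjusted p = 0.47 with an estimated correlation). Acinar genes moved with the macrophage genes (median -1.32, 0 of 25, adjusted p = 0.00025, and adjusted p = 0.57 with an estimated correlation), and 18 of the 31 groups were called, of which 0 hold with an estimated correlation and 1 was called by fry. For Batf3ko minus Rag1ko 5 genes passed in limma, with 1475 at an unadjusted p under 0.05. They were Reg3g (4.70 ± 0.56), Noxa1 (1.67), Snu13 (0.70), Ppme1 (-0.76) and the small nucleolar RNA gene Snord82 (-2.31), the last named after its values were seen. The calls of Noxa1, Snu13 and Ppme1 ended under several alternatives (adjusted p from 0.005 to 0.44, 0.0019 to 0.28 and 0.0027 to 0.21), and that of Reg3g under none (at most 0.0038). There 5 groups were called, among them the Reg family (1 of 7 higher, median 0.82, adjusted p = 0.00066) and immediate early genes (median -0.86, adjusted p = 5.5e-07), and none holds with an estimated correlation.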

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

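The test of handling was chosen before its result was seen. Those of inflammation, linked DNA, the clock genes and the other splits were chosen only after theirs.

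All 13 immediate early and isolation stress genes were higher in NOD than in either knockout at 6 weeks. Inflammation of the islets as the whole cause is argued against by the 8-week islets, where the interferon-gamma group differed more but the median of these genes was -0.75 in NOD minus Rag1ko, with 7 of 9 called genes lower in NOD. Handling of the islets before lysis, which could differ from mouse to mouse, stays open: the deviations of the genes from their group means correlated at 0.67 on average, against a median of 0.04 and a 95th percentile of 0.13 in 10000 random lists. That value shows that the genes vary together between mice of a group, not that handling differed between the genotypes. An effect of genotype at 6 weeks alone stays open as well and was not tested.

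A set of 19 genes, Rsph1, Sdc2, Cd44 and Dennd4a among them, stood apart in Rag1ko from both other genotypes at 8 weeks with differences of the same sign at 6 weeks, and 13 genes, Acadl and Lancl1 among them, stood apart in Batf3ko. DNA of the donor strain carried along beside the engineered gene is argued against as the cause for most of them, since 16 genes of the Rag1ko set (18 without Rag1 itself) and 11 of the Batf3ko set lie on other chromosomes. On the chromosome of Rag1 lie 2 genes, Ccdc141 and Cd44 (random sets a median of 1 and a 95th percentile of 4). On that of Batf3 lie 2, Acadl and Lancl1 (random sets 1 and 2). For these genes linked DNA and an effect of the knockout cannot be told apart. A first version of this test, replaced after its result was seen, took the 100 nearest genes on each side. It found 1 gene, Cd44, near Rag1 and 0 genes near Batf3. Segments elsewhere in the genome that differ between the colonies may account for part of the set, as 1 pair of adjacent genes, Rsph1 and Slc37a1, was found where 2.35% of random sets hold as many. Probes that bind a strain variant and effects of the engineered genes stay open for the rest.

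Clock genes stood apart in Rag1ko at 6 weeks. Relative to Rag1ko, the 10 genes of the negative limb and output had a median of 1.16 in Batf3ko and the 4 of the positive limb -1.13, a difference of 2.29 where random lists gave -0.22 to 0.23. The same difference was 2.24 in NOD minus Rag1ko at 6 weeks, 1.22 and 0.54 at 8 weeks in Batf3ko and NOD minus Rag1ko, and -0.2 and 0.43 in Batf3ko minus NOD at 6 and 8 weeks. The list includes the genes in which the pattern was first seen, so that the difference of 2.29 restates it and does not test an explanation. The hour at which islets were taken is not given in the sources used here and cannot be told apart from genotype, and a change of the clock in mice without lymphocytes was not tested.

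The difference between genotypes changed with age for 726 genes in NOD minus Rag1ko, 377 in Batf3ko minus NOD and 5 in Batf3ko minus Rag1ko, by a test of the interaction, and for 20, 18 and 5 lists, of which 2, 0 and 0 hold with an estimated correlation. Among the genes of NOD minus Rag1ko were Reg3g (4.49), Plac8 (2.96), C4b (2.91), Dpt (2.86), Lum (2.73), Atf3 (-4.20), Fosb (-4.20), Fam71a (-3.91), Polg2 (-3.83) and Nr4a1 (-3.18). Among those of Batf3ko minus NOD were Npas4 (3.33), Atf3 (3.16), Fam71a (3.03), Rgs2 (2.78), Gem (2.78), Lcp1 (-2.70), Plac8 (-2.64), S100a6 (-2.21), Fam111a (-1.81) and Anxa2 (-1.70), and in Batf3ko minus Rag1ko Reg3g (4.70), Noxa1 (1.67), Snu13 (0.70) and Ppme1 (-0.76). The calls of C4b, Dpt and Lum, of Atf3, Rgs2, Lcp1, Plac8, S100a6, Fam111a and Anxa2 in Batf3ko minus NOD, and of Noxa1, Snu13 and Ppme1 ended under at least 1 alternative. The lists that hold are the endothelial (median 0.34) and immediate early lists (-2.48) of NOD minus Rag1ko.

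Of 93 groups of 6 mice tested for list scores 5 had a mouse far from the others, and of 147 groups tested for named genes 5, where chance gives about 1 in 20 groups. The gap to the nearest mouse, as a share of the range of the group, was 0.642 for the T cell score of Rag1ko mouse 5 (lowest), 0.64 for the interferon-gamma score of Batf3ko mouse 1 (highest) and 0.64 for the score of other endocrine cells of NOD mouse 5 (lowest). It was 0.675 for the endothelial score of Batf3ko mouse 1 (lowest) and 0.628 for the Schwann cell score of Rag1ko mouse 1 (highest). For genes it was 0.638 for Cd3g in Batf3ko mouse 2 (lowest), 0.673 for Dnase1l3 in Rag1ko mouse 6 (lowest), 0.675 for Zbtb16 and 0.67 for Cry2 in Batf3ko mouse 6 (highest) and 0.658 for Sox4 in Rag1ko mouse 1 (highest), all at 8 weeks.

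Other splits of the same arrays were counted for each comparison, with the real split included. At 8 weeks 1 of 100 splits, the real one, gave as many genes in each, which makes chance unlikely. The counts were 812 for NOD minus Rag1ko (highest other 383), 1527 for Batf3ko minus NOD (508) and 101 for Batf3ko minus Rag1ko (9). Between the ages 1 of 84 splits gave as many in each genotype, with 10886, 9192 and 9547 genes against 731, 131 and 36. That makes chance unlikely and does not exclude the normalization. At 6 weeks 10 splits are too few for a share under 5%, with 772 genes (highest other 1), 194 (0) and 70 (101), and in these 1, 1 and 2 splits gave as many. For the interactions a first set of 100 splits mixed the ages within a genotype, so that differences between the ages turned into interactions, and its counts decide nothing: 5, 2 and 5 splits gave as many as the real 726, 377 and 5 in NOD minus Rag1ko, Batf3ko minus NOD and Batf3ko minus Rag1ko, with highest others of 5054, 1024 and 1744, which point to a structure of the samples. A second set of 100, drawn after these counts were seen, exchanged genotypes within each age, which tests for any effect of genotype. As many genes were found in 1 split for NOD minus Rag1ko (highest other 546), in 1 for Batf3ko minus NOD (61) and in 13 for Batf3ko minus Rag1ko (88). A genotype difference shared by both ages also sets the real split apart, so these splits cannot exclude chance for any of the interactions.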

How the results depend on the processing

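All tests here were planned except the fit of arrays of the same age. Counts are limited by the number of mice, the confounding of age and normalization, and dim probe sets (11809 of 19938 genes pass the filter). Under quantile normalization across the 27 arrays 21 of 21 counts stayed within 1.5 times, 175 of 186 list shifts kept their direction and their side of the threshold, and of 167 named genes 162 kept both, 3 lost the threshold, 1 gained it and 1 reversed. With array weights 164 of 167 named genes kept both, with the acinar covariate 159, with only the groups compared 142 (25 lost the threshold), and all 142 tested without dim genes did. With 1 array left out 1774 cases kept both, 82 lost the threshold and 4 gained it. Where no cause is stated below, none was tested.

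Without dim genes 3 lists were called between Batf3ko and Rag1ko at 6 weeks, 5263, 5118 and 5319 genes differed between the ages in NOD, Batf3ko and Rag1ko (fewer genes were tested), and 24 genes passed the interaction of Batf3ko minus Rag1ko. With every probe set tested, 117 probe sets differed between Batf3ko and Rag1ko at 6 weeks, 16441 between the ages in NOD (more features were tested), and the interactions of NOD minus Rag1ko and Batf3ko minus Rag1ko gave 1211 and 48. With trend and robust variances the latter gave 42. With array weights the 6-week counts were 1965, 495 and 448 for NOD minus Rag1ko, Batf3ko minus NOD and Batf3ko minus Rag1ko, with 3 lists in the last, and the interactions in the same order gave 1318, 830 and 108. With quantile normalization the log2 difference of Rag1 between the ages in NOD turned from -0.47 to 0.06 (adjusted p = 0.75; range over its alternatives 0.0043 to 0.75), since that scaling lifts the 8-week arrays.

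With a 2-fold threshold, which by construction passes fewer genes, the 8-week counts were 188 for NOD minus Rag1ko, 199 for Batf3ko minus NOD and 12 for Batf3ko minus Rag1ko, the 6-week counts 132, 83 and 22, the age counts 1364, 775 and 934 in NOD, Batf3ko and Rag1ko, and the interactions 181, 95 and 3. Genes shared by the NOD comparisons then numbered 161. Without that fold threshold they numbered 102 and 155 when the NOD mice were split between them (fewer arrays). With mice 1 to 3 of the 8-week groups (fewer arrays) the 8-week counts were 173, 428 and 15 and the interactions 360, 148 and 1. With the acinar score as a covariate 912 genes differed in Batf3ko minus NOD at 8 weeks, 6702, 2754 and 3387 between the ages, and 192 and 8 in the interactions of Batf3ko minus NOD and Batf3ko minus Rag1ko. The mean of the Reg family in Batf3ko minus NOD at 8 weeks then turned from -0.09 to 0.81 (adjusted p = 0.021; range over its alternatives 0.021 to 0.92).

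With only the groups compared in the fit (fewer residual degrees of freedom) the 8-week counts were 317, 757 and 46, the 6-week counts 197, 39 and 2, and the interaction of Batf3ko minus NOD gave 182. The arrays of the same age alone gave 52 for Batf3ko minus Rag1ko at 8 weeks and 476, 127 and 8 at 6 weeks. An estimated correlation left 0 lists for Batf3ko minus Rag1ko at 8 weeks (3 with the preset one) and 1, 2 and 0 at 6 weeks, where fry gave 0 at 8 weeks and 5, 3 and 1 at 6 weeks.

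With the replicate number as a block the counts stayed within 1.5 times in 17 of 18 cases, and Batf3ko minus Rag1ko at 6 weeks gave 45. Mice that share a number were not paired in the values, since the correlations of 27 such pairs ran from -0.21 to 0.25 with 1 over 0.1.

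With 1 array left out the counts ran from 473 to 1022, 1101 to 1561 and 60 to 113 at 8 weeks for NOD minus Rag1ko, Batf3ko minus NOD and Batf3ko minus Rag1ko, from 377 to 761, 63 to 308 and 33 to 53 at 6 weeks, from 9329 to 10729, 7471 to 9035 and 7826 to 9373 between the ages, and from 393 to 803, 75 to 436 and 1 to 9 in the interactions. Called lists ran over 24 to 24, 22 to 22 and 3 to 4 at 8 weeks and 12 to 16, 15 to 18 and 3 to 6 at 6 weeks. Scores past the threshold ran over 19 to 23, 17 to 21 and 0 to 3. NOD minus Rag1ko at 8 weeks gave 481 and 473 without NOD mice 5 and 6. Batf3ko minus Rag1ko at 8 weeks gave 63, 64 and 61 without Batf3ko mice 1, 3 and 5, 60 and 67 without Rag1ko mice 3 and 6, and 3 scores without Batf3ko mouse 1. At 6 weeks NOD minus Rag1ko gave 377 without NOD mouse 2 and 500 and 477 without Rag1ko mice 2 and 3. Batf3ko minus NOD gave 99 without NOD mouse 2 and 308, 76 and 63 without Batf3ko mice 1, 2 and 3, and Batf3ko minus Rag1ko gave 39 (3 lists) and 33 without Batf3ko mice 2 and 3 and 36 without Rag1ko mouse 2. Among the interactions, NOD minus Rag1ko gave 393 without NOD mouse 2 of 6 weeks, and Batf3ko minus NOD 170, 227, 102 and 75 without NOD mice 2 and 3 and Batf3ko mice 2 and 3 of 6 weeks. Batf3ko minus Rag1ko gave 1 without Batf3ko mouse 2 and 9, 8 and 8 without Rag1ko mice 1, 2 and 3 of 6 weeks, and 8 and 9 without Batf3ko mouse 2 and Rag1ko mouse 1 of 8 weeks.

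The Rag1 difference of NOD minus Rag1ko at 6 weeks, not past the threshold with all arrays, passed it without Rag1ko mouse 1 (-0.72, adjusted p = 0.013), with array weights (-0.66, 0.0037) and with quantile normalization (-0.58, 0.045), over a range of 0.0037 to 0.53. Batf3ko minus Rag1ko at 8 weeks lost Nr1d2 without Rag1ko mouse 3 (adjusted p = 0.054; range 0.0083 to 0.15), and Polg2, Fam111a and Rab31 each under several single arrays left out (highest adjusted p 0.26, 0.22 and 0.09). At 6 weeks Reg3a of Batf3ko minus Rag1ko was lost without Batf3ko mouse 3 (adjusted p = 0.14; range 0.00048 to 0.38). Scores that crossed the threshold with 1 array left out included B cell, regulatory and immediate early genes in NOD minus Rag1ko and plasma cell genes in Batf3ko minus NOD.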

Other observations

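The array weights below were picked after they were seen, and no tests were run on them. They were lowest at 6 weeks for Rag1ko mouse 1 (0.55) and NOD mouse 2 (0.66).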
